A study of Rattus norvegicus with 48 samples.

How the data were processed

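Gene expression was measured with 1-colour Affymetrix whole-transcript arrays in 4 brain areas of adult male rats. Per the labels' protocols, each array took biotin-labelled DNA made from RNA pooled from 4 animals, and each pool stands for a set of 4 dyads, a dyad being a control-lineage and a vinclozolin-lineage rat housed together. Dyad groups 1 to 3 were not stressed (NSt) and dyad groups 4 to 6 were stressed (St), and the lineages are written Con and Vin. The pools of a dyad group supplied all 4 areas. The replicate number therefore links the vinclozolin and the control pool of a stress condition, and links no stressed pool to a non-stressed one.

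The deposited values are on the log2 scale. The submitters' processing notes name Partek and RMA, a method that corrects background, normalizes arrays to a common distribution and summarises probe sets, with versions not given in the sources used here. Array medians were alike within an area and differed between areas, so groups were compared within an area, and levels of 2 areas are set side by side only for tissue markers and for the difference of CA3 from CA1. Arrays carry no read depth, and their number limits the precision.

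The value table has 27342 probe sets. The platform annotation gives 15097 of them 1 gene symbol, 323 several and 11922 none, with 14324 distinct symbols; 15067 entries were matched by gene number to the RefSeq annotation of assembly GRCr8, which changed 0 symbols. Probe sets with several symbols or none were tested but not named, and no coordinates are given because the build behind the probe sets is not given in the sources used here. Of the probe sets, 319 hold the same values as another one in every array used.

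Of the 48 deposited arrays, 46 were used. The second NSt-Vin array of motor cortex and the third St-Con array of CA1 equal, on all 27342 probe sets, the mean of the remaining arrays of their group, with a largest deviation of 0.005 against a tolerance of 0.0051. Among the other 46 arrays at most 6.82% of the probe sets do so, and the largest deviation in an array is at least 0.935. A mean of other replicates adds no measurement of its own, so these 2 arrays were left out and their groups have n = 2, which leaves the group means unchanged. This departs from the design fixed before the data were examined, which used all 48 arrays, and it was decided after the values and the results with 48 arrays had been seen; both counts are given wherever they differ. The labels do not say how these values arose.

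Group means were fitted per area with limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the log2 values as deposited, with all groups of the area sharing one estimate of the spread. A further fit used the mean of the 4 areas of each pool, over the 10 pools measured in all 4 areas. Each fit gave 7 two-sided comparisons: the lineage difference without stress and with stress, the stress difference in each lineage, the interaction, and both averages. Adjusted p-values are Benjamini-Hochberg values over all probe sets, with a threshold of 0.05. A limma F test asked whether a lineage or stress effect differs between areas, with the animal pool as a block. Standard errors (SE) come from the fit, and SD is the spread between arrays or dyad groups. The pools hold different animals, so p-values measure the spread between pools.

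Gene lists were fixed before the data were examined: 16 of gene functions and 16 of cell types, 32 in all, tested with limma's camera against all other genes at its preset correlation of 0.01 and again with a correlation estimated from the data (statmod 1.5.0 was used for blocks). Adjustment was over the lists of 1 area and comparison. Of the 1120 list tests, 270 passed at the preset correlation and 0 with the estimated correlation, so every list shift given below as passed rests on the preset correlation. Counts "adjusted over the list alone" adjust the p-values of a list's members among themselves. Named genes follow a rule fixed at the same time: the 6 highest and 6 lowest log2 differences past the threshold with 1 symbol per comparison within an area, list members past the threshold up to 6, the 3 smallest p-values where fewer than 3 passed, and fixed control genes.

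The pairing of vinclozolin and control pools comes from the labels, since they were cage mates. It was checked on the deviations of the arrays from their group means: pools of the same dyad group correlated above 0.1 in 6 of 6 pairs in the basolateral amygdala, 3 of 5 in motor cortex, 5 of 5 in CA1 and 5 of 6 in CA3, with medians of 0.508, 0.22, 0.279 and 0.31, while other pairs had medians of -0.29, -0.124, -0.154 and -0.181. Fits with this replicate block are given beside a result where they change it.

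Alternatives planned before the data were examined were a filter on probe sets below the 30th percentile, the replicate block, scan day as a block or within a scan day, eBayes with trend and robust settings, quantile normalization, one fit of all areas, an estimated list correlation and leaving out each pool in turn. Those added after seeing the data were identical probe sets counted once, leaving out 5 arrays rich in choroid plexus transcripts (list mean over 0.6 above the area mean), keeping the averaged arrays, the replicate block with an estimated list correlation, and pools averaged after centring each area.

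Simulated tests had 27342 genes, the real spread and 200 changed genes. For stress in the vinclozolin lineage in CA1, 57% of changes of 0.4 and 93% of those of 0.8 were recovered with 9 false calls. For lineage without stress in the amygdala the shares were 43% and 96% with 4 false calls, and for the lineage average over the mean of areas 94% and 99% with 5. A list shift of 0.1 in the immediate early genes was called in 20 of 20 runs with both correlations, against 4 of 620 tests of other lists. Real lists depended on the correlation, so their rates may differ.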

Results

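Gene expression was measured on whole-transcript arrays in 4 brain areas of adult male Sprague-Dawley rats of the F3 generation, 3 generations after exposure of pregnant F0 females. The vinclozolin lineage (Vin) descends from females given 100 mg/kg/day of vinclozolin, a fungicide with anti-androgenic action, on embryonic days 8 to 14, and the control lineage (Con) from females given the vehicle. Rats were restrained for 6 hours a day over 21 days in adolescence (St) or left unrestrained (NSt), and brains were taken at 120 days of age. Punches of 2 mm came from the basolateral amygdala, motor cortex, CA1 and CA3, and each array holds RNA pooled from 4 rats. Every area has 4 groups (NSt-Con, NSt-Vin, St-Con and St-Vin) of 3 arrays. In motor cortex NSt-Vin and in CA1 St-Con 1 of the 3 arrays equals the mean of the other two, so n = 2 there and 46 of 48 arrays were used. Values are RMA log2 signals, and differences are log2 differences from limma with their SE. Arrays of an area correlated at 0.975 or more. The median SD between replicates lay between 0.084 and 0.0999. In CA1 St-Vin alone was scanned on day 4 and the other groups on day 3, so any CA1 difference that involves St-Vin, the interaction and both averages included, may be one of scan day. In motor cortex NSt-Con was scanned on day 1 and both stressed groups on day 2.

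Markers of neighbouring tissue varied between punches. Ttr, the thyroid hormone carrier made by choroid plexus, ranged from 7.38 to 15.59 in CA1 and from 4.22 to 15.02 in motor cortex. The choroid plexus list (17 genes) stood over 0.6 above its area mean in 5 arrays, by 2.08 in motor cortex NSt-Con 1, 0.684 in CA1 NSt-Con 2, 2.19 in CA1 NSt-Con 3, 2.23 in CA3 NSt-Con 3 and 0.694 in amygdala St-Vin 3. Choroid plexus genes were lower in both groups set against NSt-Con in motor cortex, CA1 and CA3. In the amygdala, markers of striatal medium spiny neurons followed the dyad group. The striatal list (18 genes) averaged 9.08, 7.84 and 7.48 in dyad groups 1 to 3 (not stressed) and 9.23, 9.25 and 7.44 in dyad groups 4 to 6 (stressed), while the 2 lineages of a dyad group differed by 0.074 to 0.348. Averaged over stress, 17 of its 18 genes were lower in the vinclozolin lineage (mean -0.14, adjusted p = 0.251, or 9.22e-12 with the replicate block, while 0 lists passed with both the block and an estimated correlation).

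**Figure D1:**
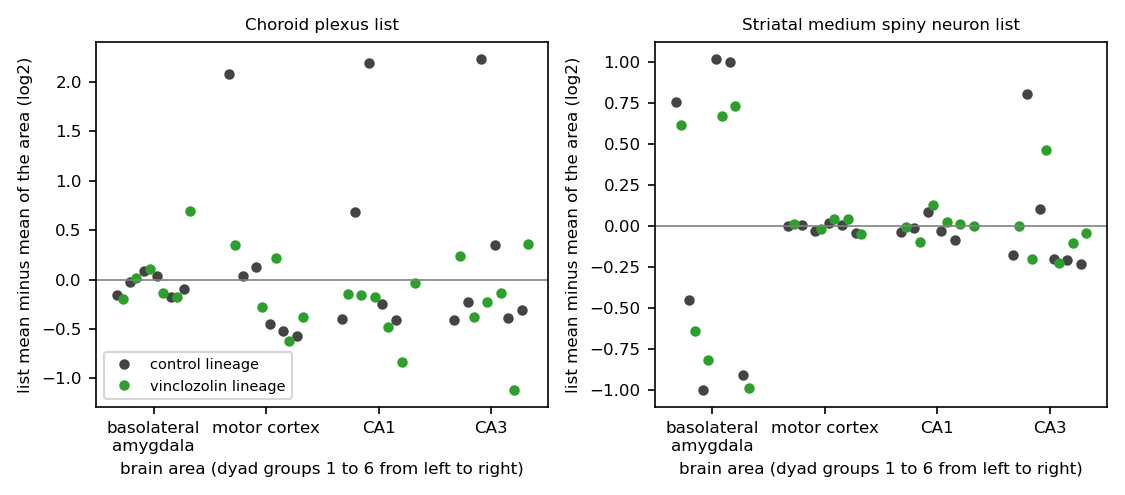
Mean log2 signal of the choroid plexus list (left) and the striatal medium spiny neuron list (right) in each of the 46 arrays, as the difference from the mean of its brain area; each point is 1 array, coloured by lineage, with dyad groups 1 to 6 from left to right. The choroid plexus list stands over 2 above the area mean in 1 array each of motor cortex, CA1 and CA3, and the striatal list of the amygdala spreads by dyad group.

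Among rats that were not stressed, immediate early genes, which neurons switch on when active, were higher in the vinclozolin lineage in 3 of the 4 areas. In the amygdala 20 of the 27 list members were higher (mean 0.066, adjusted p = 0.0112), with Npas4, an activity-dependent transcription factor, at 0.27 ± 0.098 (n = 3 and 3, limma). In motor cortex 21 were higher (mean 0.092, adjusted p = 0.0279) and in CA3 24 (mean 0.10, adjusted p = 0.0156). With an estimated correlation the adjusted p values were 0.995, 0.889 and 0.666. These shifts rested on few arrays. In the amygdala, markers of dentate granule cells (mean -0.15, adjusted p = 0.0165) and CA1 cells (-0.19, 0.0247) were lower too, at 0.995 and 0.814 with an estimated correlation. The amygdala mean was -0.0031 without NSt-Vin 2 (adjusted p = 0.556) and 0.014 without NSt-Con 3 (0.229), and the CA3 mean 0.030 without NSt-Vin 3 (0.792) and 0.087 without NSt-Con 1 (0.0814). The motor cortex mean was 0.064 without NSt-Vin 3 (0.314), 0.075 without NSt-Con 2 (0.171) and 0.079 without NSt-Con 1 (0.0866). In CA1 23 were higher (mean 0.096, adjusted p = 0.144, or 0.000692 with the replicate block, while 0 lists passed with the block and an estimated correlation). Oligodendrocyte and myelin genes were lower in CA1, all 21 of them (mean -0.18, adjusted p = 1.17e-08, or 0.73 with an estimated correlation), and the 15 circadian clock genes were higher (mean 0.12, adjusted p = 0.0109, or 0.73 with an estimated correlation). Markers of other tissue passed beside them, with means of -0.24 for leptomeninges (4.84e-05), -0.093 for thalamus and habenula (0.0192), -0.088 for blood cells (0.0354), -0.042 for endothelium (0.0344) and 0.080 for astrocytes (0.00645), all 0.73 with an estimated correlation. Of these 5 lists, astrocytes alone passed without the choroid-rich arrays. The clock mean turned to -0.028 without the choroid-rich arrays (adjusted p = 0.589), and was 0.013 without NSt-Con 3 (0.908) and 0.050 without NSt-Vin 1 (0.108). In CA3, 17 of the 18 cholesterol synthesis genes were higher (mean 0.11, adjusted p = 0.000136, or 0.666 with an estimated correlation). Leptomeninges (-0.20, 0.00104), striatal (-0.16, 0.0172), thalamic and habenular (-0.066, 0.0418) and endothelial genes (-0.044, 0.0113) were lower, at 0.666, or 0.786 for striatal genes, with an estimated correlation. In motor cortex GABA genes (17 of 20 higher, mean 0.074, adjusted p = 0.014) and ribosomal protein genes (57 of 74 higher, mean 0.055, adjusted p = 0.000611, or 0.118 with the replicate block) were higher, both with adjusted p = 0.889 with an estimated correlation. The GABA mean was 0.046 without NSt-Vin 1 (adjusted p = 0.144) and the ribosomal mean 0.037 without NSt-Con 2 (0.144). Choroid plexus genes, 17 of 17, were lower in motor cortex (mean -0.71), CA1 (mean -0.98) and CA3 (mean -0.65), and without the choroid-rich arrays these means were -0.047, 0.24 and 0.20.

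No single gene passed in this comparison. limma called 0 of 27342 probe sets in each area, with 572 below an unadjusted p of 0.05 in the amygdala, 1554 in motor cortex, 898 in CA1 and 1470 in CA3, where chance alone gives 1367. The nearest were Or6c219 (0.75 ± 0.097, adjusted p = 0.144) in motor cortex and Epha5, an ephrin receptor (0.26 ± 0.051, adjusted p = 0.845), in CA3. None of the members of the immediate early gene list passed when adjusted over the list alone in these 4 areas. In motor cortex only 1 NSt-Vin array shares scan day 1 with NSt-Con. Scan day as a block amounts to leaving out the other one, NSt-Vin 3, and takes the spread of the lone array from the other groups: the means were 0.064 for immediate early genes (adjusted p = 0.314), 0.10 for GABA genes (0.0218) and 0.063 for ribosomal proteins (0.0103).

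Among stressed rats, immediate early genes were higher in the vinclozolin lineage in motor cortex, as without stress, and in CA1. In motor cortex 21 of 27 members were higher (mean 0.11, adjusted p = 0.00218, or 0.893 with an estimated correlation), and 2 of them passed when adjusted over the list alone, against 0 over all genes. Ccn1, a matricellular protein, led at 0.27 ± 0.064 (n = 3 and 3). The mean was 0.063 without St-Vin 2 (adjusted p = 0.208) and 0.089 without St-Con 3 (0.119). Leptomeninges were higher as well, 16 of 16 (mean 0.15, adjusted p = 0.0331), or -0.088 without St-Vin 3 (0.00187) and 0.12 without St-Con 3 (0.203). In CA1 19 of 27 were higher (mean 0.21, adjusted p = 0.0203, or 0.922 with an estimated correlation). Without St-Con 1, St-Con 2, St-Vin 1 or St-Vin 2 that list no longer passed (means 0.23, 0.19, 0.18 and 0.16, adjusted p = 0.0514, 0.23, 0.0671 and 0.151). Markers of other tissue passed beside it, with means of -0.23 for CA3 and CA2 cells and 0.20 for cortical layer neurons (both 0.0172) and -0.19 for ependyma (0.0128), as did clock genes at 0.14 (0.00912), all 0.922 with an estimated correlation. Oligodendrocyte and myelin genes were higher in both areas, 21 of 21 in motor cortex (mean 0.14, adjusted p = 0.00012, or 0.893 with an estimated correlation) and 21 of 21 in CA1 (mean 0.18, adjusted p = 0.00196, or 0.922 with an estimated correlation). They were lower in the amygdala, 17 of 21 (mean -0.11, adjusted p = 7.1e-08, or 0.939 with an estimated correlation), beside lower striatal genes (-0.23, 0.046, or 0.33 with 0.659 without St-Vin 3) and higher choroid plexus (0.20, 0.00295) and blood cell genes (0.24, 0.0102), all 0.939 with an estimated correlation. The motor cortex shift rests on 1 array, with a mean of 0.0025 without St-Vin 1 (adjusted p = 0.895). The CA1 mean was 0.081 without St-Con 1 (0.424), 0.092 without St-Vin 2 (0.194) and 0.13 without St-Vin 1 (0.0503). The amygdala mean was -0.056 without the choroid-rich St-Vin 3 (0.00538), -0.065 without St-Con 2 (0.00304) and -0.19 without St-Con 3 (4.84e-12). Motor cortex also showed 58 of 78 oxidative phosphorylation genes lower (mean -0.044, adjusted p = 0.000981) and 23 of 28 genes of DNA methylation and histone deacetylation higher (mean 0.048, adjusted p = 0.0234), both 0.893 with an estimated correlation. The former was at -0.0046 without St-Vin 3 (adjusted p = 0.634) and -0.028 without St-Con 3 (0.139), and the latter missed without St-Con 3, St-Vin 1 or St-Vin 2 (0.119, 0.104 and 0.105). All stressed motor cortex arrays shared scan day 2. In CA3, 28 of 34 glutamate receptor and transport genes (mean -0.063) and 13 of 15 circadian clock genes (mean -0.077) were lower, both with adjusted p = 0.0382, or 0.958 with an estimated correlation. Without St-Vin 3 these means were -0.0086 (adjusted p = 0.593) and -0.045 (0.151). The glutamate list also missed without St-Con 1 or 2 (0.0611 and 0.132), and the clock list without St-Con 3 or St-Vin 2 (0.184 and 0.104).

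Single genes did not pass in stressed rats either in the unpaired fit. limma called 0 probe sets in each area, with 705 below an unadjusted p of 0.05 in the amygdala, 1652 in motor cortex, 1359 in CA1 and 1142 in CA3. In CA1 the replicate block changed this to 347 probe sets, 193 higher and 154 lower in St-Vin. Among them Sh3bp4, an endocytic adaptor, was at 0.50 with the block (adjusted p = 0.0228) and at 0.46 ± 0.074 without it (adjusted p = 0.887, n = 2 and 3). That paired fit rests on 2 measured stressed dyad pairs, and St-Con and St-Vin of CA1 were scanned on different days, so lineage and scan day cannot be told apart there.

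Averaged over stress and over the 4 areas of each pool, the immediate early genes were the list with the smallest p-value for lineage. Of the 27 members 22 were higher in the vinclozolin lineage (mean 0.084, adjusted p = 1.66e-11, or 0.101 with an estimated correlation and 0.481 with the replicate block and an estimated correlation). Leaving out any 1 pool gave means of 0.068 to 0.10, and the list passed each time. Without the choroid-rich arrays, where no NSt-Con pool keeps all 4 areas and each area is centred on its remaining arrays, the mean was 0.067 (adjusted p = 3.36e-11). Adjusted over the list alone 6 members passed, and 0 passed over all genes. Npas4 stood at 0.34 ± 0.051 (adjusted p = 0.9997) and Fos at 0.19 ± 0.037. Within dyad groups the vinclozolin pool exceeded its control partner in 19 of 22 pairs of arrays. Averaged over areas it did so in 6 of 6 dyad groups, by 0.0923 ± 0.0206 (SD, n = 6, exact two-sided sign-flip test, p = 0.03125, the smallest that 6 dyad groups can give). By gene, Fos was higher in 21 of 22 pairs, Npas4 in 20, Junb in 19 and Dusp1, a MAP kinase phosphatase, in 18, with means over dyad groups of 0.18 ± 0.082, 0.36 ± 0.114, 0.17 ± 0.025 and 0.23 ± 0.126 (SD, n = 6). Each of these 4 genes was higher in 6 of 6 dyad groups (exact p = 0.03125, or 0.0767 after Benjamini-Hochberg adjustment over the list).

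By area, the list difference was 0.041 ± 0.0674 in the amygdala (SD, n = 6, exact p = 0.219, 4 of 6 dyad groups higher) and 0.072 ± 0.0759 in CA3 (n = 6, exact p = 0.0938, 5 of 6). In motor cortex it was 0.0969 ± 0.0329 (n = 5, exact p = 0.0625, 5 of 5) and in CA1 0.177 ± 0.117 (n = 5, exact p = 0.0625, 5 of 5). With 5 pairs no smaller p is possible. The limma list test of the lineage average passed in motor cortex (mean 0.10, adjusted p = 0.000191, or 0.0145 with scan day as a block). It passed in CA1 (mean 0.15, adjusted p = 0.00336, beside lower markers of ependyma and of CA3 and CA2 cells, both -0.13) and CA3 (mean 0.072, adjusted p = 0.000948). For the 3 areas the adjusted p was 0.813, 0.837 and 0.982 with an estimated correlation. It missed in the amygdala (adjusted p = 0.128) and passed there with the replicate block (adjusted p = 0.0186), while 0 lists did so with the block and an estimated correlation. Leaving out the choroid-rich arrays took the CA1 mean to 0.058 (adjusted p = 0.491), and leaving out NSt-Con 3 alone to 0.097 (0.107). The CA3 mean was 0.035 without NSt-Vin 3 (0.184) and 0.041 without St-Vin 3 (0.267).

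**Figure D2:**
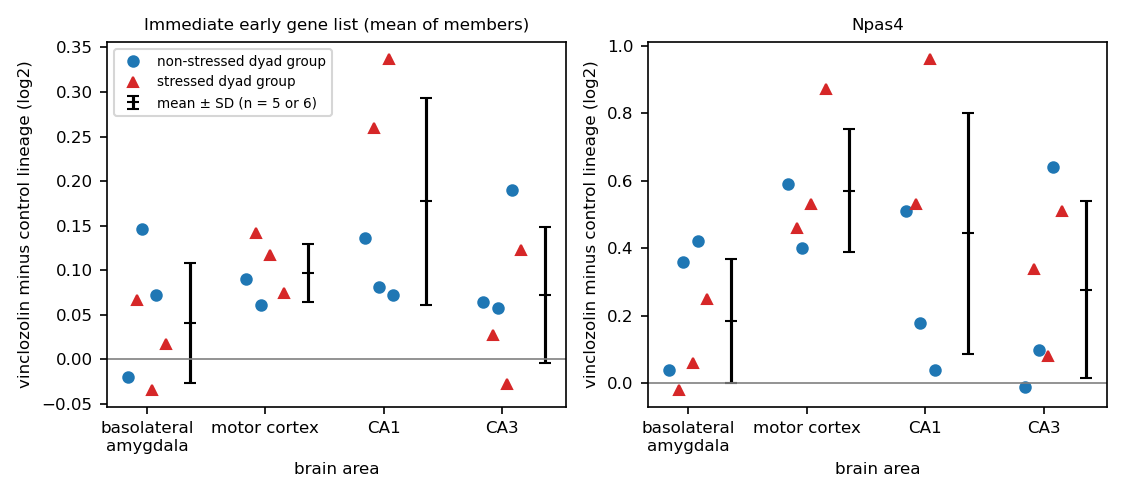
Vinclozolin minus control difference (log2) within each dyad group and brain area, for the mean of the 27 immediate early genes (left) and for Npas4 (right); points are single dyad groups, by stress condition, and bars give the mean ± SD over 5 or 6 dyad groups. The list difference lies above 0 in 19 of 22 pairs and that of Npas4 in 20 of 22.

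Other lists passed for the lineage average of the 4 areas as well. St-Vin of CA1, scanned on a day of its own, enters these means. All 13 genes of CA3 and CA2 pyramidal cells were lower (mean -0.050, adjusted p = 0.000686, or 0.152 with an estimated correlation, and mean -0.013 with adjusted p = 0.294 without the choroid-rich arrays), as were 59 of 78 oxidative phosphorylation genes (mean -0.018, adjusted p = 9.03e-06, or 0.932 with an estimated correlation). The oxidative phosphorylation mean turned to 0.014 without NSt-Vin 3 (adjusted p = 0.887) and was -0.051 without NSt-Vin 1 (3.01e-17). Cholesterol synthesis genes were higher, 15 of 18 (mean 0.028, adjusted p = 0.0103, or 0.932 with an estimated correlation and 0.115 with the replicate block). They missed without NSt-Vin 1 (mean -0.0035, adjusted p = 0.911), NSt-Con 2 (0.166), St-Con 1 (0.0611) or St-Vin 1 (0.141). Choroid plexus genes were lower, 17 of 17 (mean -0.28, adjusted p = 1.63e-09, or 0.932 with an estimated correlation, and mean 0.025 without the choroid-rich arrays). None of the fixed control genes passed (adjusted p = 0.9997 each). Bdnf was at 0.098 ± 0.023 and Nr3c2 at -0.051 ± 0.053. Nr3c1, the glucocorticoid receptor, was at 0.032 ± 0.058, Crh at 0.0058 ± 0.037 and Esr1 at 0.021 ± 0.028. Dnmt1 was at 0.040 ± 0.039, Dnmt3a at -0.020 ± 0.024 and Fkbp5, a co-chaperone of the glucocorticoid receptor, at -0.054 ± 0.045. limma called 0 probe sets for the lineage average in each area and in the mean of areas, with 983, 1578, 1164, 940 and 811 below an unadjusted p of 0.05 in the amygdala, motor cortex, CA1, CA3 and the mean. With the replicate block CA1 gave 112 probe sets, 74 higher and 38 lower, among them Prcp, a lysosomal carboxypeptidase, at 0.34 (0.33 ± 0.065 without the block, adjusted p = 0.994). Their stressed part again rests on 2 measured pairs with the lineages on different scan days. Lineage effects that differ between areas numbered 0 of 27342 in the F test (1316 below an unadjusted p of 0.05). Igfbp6, an insulin-like growth factor binding protein, came nearest (adjusted p = 0.123), at -0.63 in motor cortex, -0.17 in the amygdala, -0.095 in CA1 and -0.11 in CA3.

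In motor cortex of the control lineage stressed and non-stressed rats differed, on arrays scanned on different days. limma called 174 probe sets, 76 higher and 98 lower in St-Con than in NSt-Con (n = 3 and 3), of which 74 carry 1 gene symbol, 27 higher and 47 lower. The MHC class I gene RT1-CE2 rose by 0.59 ± 0.083 (adjusted p = 0.022), Rnf135, a ubiquitin ligase, by 0.77 ± 0.146 (0.0452), the histone gene H4c14 by 0.45 ± 0.072 (0.0289), and Agt, the angiotensin precursor made by astrocytes, by 0.42 ± 0.072 (0.0404). Igfbp6 fell by 0.66 ± 0.127 (0.0463), Fam133b by 0.61 ± 0.112 (0.0432), the MHC gene RT1-S2 by 0.57 ± 0.110 (0.0463) and Larp7, an RNA-binding protein, by 0.44 ± 0.088 (0.0498). The highest difference was that of Or6c219, an olfactory receptor gene, at 0.80 ± 0.087 (0.0181), from 5.28 ± 0.050 to 6.08 ± 0.185 (SD). Fkbp5 was at 0.38 ± 0.091 (adjusted p = 0.0717), Nr3c1 at -0.083 (0.522) and Crh at 0.12 (0.292). The same comparison on all 48 deposited arrays gave 1027 probe sets.

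Among the lists, 57 of 74 ribosomal protein genes were higher with stress in control-lineage motor cortex (mean 0.065, adjusted p = 6.08e-05, 4 adjusted over the list alone). So were 11 of 15 astrocyte genes (mean 0.090, adjusted p = 0.0125, 1 adjusted over the list alone) and 12 of 15 circadian clock genes (mean 0.086, adjusted p = 0.0265, 2 adjusted over the list alone). Choroid plexus genes were lower, 17 of 17 (mean -1.26, adjusted p = 1.25e-06, 12 adjusted over the list alone), led by Ttr at -6.35 ± 1.58. All 4 lists had adjusted p = 0.992 with an estimated correlation. The astrocyte mean was 0.066 without NSt-Con 1 (adjusted p = 0.0837), 0.049 without NSt-Con 2 (0.221) and 0.054 without St-Con 1 (0.197). The clock mean was 0.067 without NSt-Con 1 (0.0837), 0.068 without NSt-Con 2 (0.221) and 0.082 without St-Con 2 (0.0634), and the choroid plexus mean -0.60 without NSt-Con 1 (0.000274). NSt-Con was scanned on day 1 and St-Con on day 2. With scan day as a block, which only the 2 NSt-Vin arrays inform, 0 probe sets passed. The mean change of the 174 in their own direction was 0.414 ± 0.143 before and 0.426 ± 0.209 after (SD over probe sets), their median SE rose from 0.0633 to 0.129, and 174 of 174 had the same sign. With that block the ribosomal mean was 0.081 (adjusted p = 0.00565), the astrocyte mean 0.17 (0.00565), the circadian mean 0.097 (0.158) and the choroid plexus mean -0.63 (0.138). Leaving out NSt-Con 1, 2 or 3 left 19, 4 and 0 probe sets, and leaving out St-Con 1, 2 or 3 left 0, 13 and 19.

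**Figure D3:**
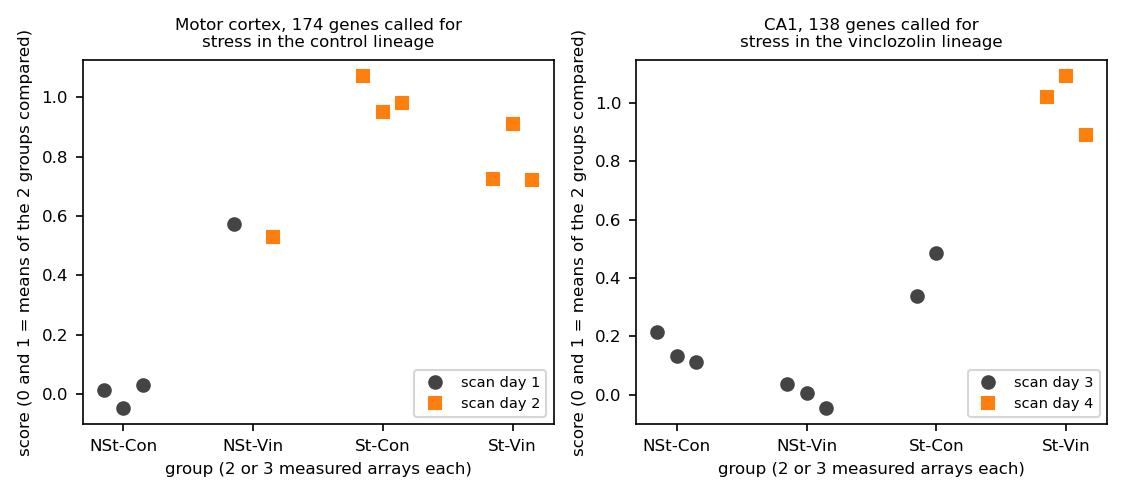
Score of each array (y axis, no unit) on the 174 probe sets called for stress in the control lineage of motor cortex (left) and on the 138 called for stress in the vinclozolin lineage of CA1 (right); the probe sets were chosen on the 2 groups whose means set 0 and 1, so only the other 2 groups are free. Points are single arrays by group and scan day, and the NSt-Vin arrays of motor cortex lie at 0.574 (scan day 1) and 0.529 (scan day 2).

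In CA1 of the control lineage, stressed rats had lower oxidative phosphorylation genes, 63 of 78 (mean -0.081, adjusted p = 4.89e-07), and lower glucocorticoid-responsive genes, 15 of 20 (mean -0.10, adjusted p = 0.00283). Astrocyte genes were lower, 14 of 15 (mean -0.11, adjusted p = 0.00185), and circadian clock genes higher, 14 of 15 (mean 0.15, adjusted p = 0.00031). With an estimated correlation the adjusted p of these lists was 0.592, except 0.534 for the glucocorticoid-responsive genes. Choroid plexus genes, 17 of 17, were lower as well (mean -1.16, adjusted p = 5.7e-10, or 0.592 with an estimated correlation). So were leptomeninges (-0.28, 0.00185), ependyma (-0.20, 0.00283), blood cells (-0.16, 0.0251) and endothelium (-0.073, 0.0441), while cortical layer neurons were higher (0.12, 0.0398), with 0.592 and, for the last, 0.603 with an estimated correlation. Without the choroid-rich NSt-Con arrays 2 and 3, which leaves 1 NSt-Con array, of these 5 only blood cells passed, the choroid plexus mean was 0.069, the circadian mean 0.0087 (adjusted p = 1), the glucocorticoid mean -0.066 (0.162) and the astrocyte mean -0.057 (0.305). Without NSt-Con 3 alone the clock mean was 0.050 (0.155). Without St-Con 2, which leaves 1 array, the means were -0.034 for oxidative phosphorylation (0.188), -0.084 for glucocorticoid-responsive genes (0.0731) and -0.11 for astrocytes (0.0709). In CA3 all 21 oligodendrocyte genes (mean -0.24, adjusted p = 0.000236) and 17 of 18 striatal genes (mean -0.46, adjusted p = 4.63e-08) were lower, both 0.976 with an estimated correlation. The oligodendrocyte mean was -0.086 without the choroid-rich NSt-Con 3 (adjusted p = 0.41), -0.45 without NSt-Con 2 (2.4e-09), -0.19 without St-Con 1 (0.0853), -0.14 without St-Con 2 (0.134) and -0.40 without St-Con 3 (2.93e-11). The striatal mean was -0.18 without NSt-Con 2 (0.0784). In the amygdala 54 of 74 ribosomal protein genes were higher (mean 0.037, adjusted p = 2.05e-06) and 17 of 18 cholesterol synthesis genes lower (mean -0.10, adjusted p = 0.000861), both 0.715 with an estimated correlation. The cholesterol mean was -0.059 without St-Con 1 (adjusted p = 0.129) and -0.077 without NSt-Con 3 (0.0838). Beside them 18 of 18 striatal genes were higher (mean 0.60, adjusted p = 2.05e-06, or 0.715 with an estimated correlation). limma called 0 probe sets for stress in the control lineage in these 3 areas, with 847 (amygdala), 889 (CA1) and 975 (CA3) below an unadjusted p of 0.05.

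In CA1 of the vinclozolin lineage stressed and non-stressed rats differed, on arrays scanned on different days. limma called 138 probe sets, 26 higher and 112 lower in St-Vin than in NSt-Vin (n = 3 and 3), of which 77 carry 1 symbol, 10 higher and 67 lower. Rxfp1, a relaxin receptor, rose by 0.85 ± 0.124 (adjusted p = 0.0447), Igfbp5 by 0.77 ± 0.139 (0.0495), Tgfb2, a growth factor, by 0.70 ± 0.102 (0.0447) and Sh3bp4 by 0.59 ± 0.066 (0.0447). Anxa6, a membrane-binding annexin, fell by 1.01 ± 0.160 (0.045), Drc12, of motile cilia, by 0.85 ± 0.143 (0.045), Eif4e3, a cap-binding protein, by 0.68 ± 0.109 (0.045) and Gabrg1, a GABA-A receptor subunit, by 0.61 ± 0.102 (0.045). Mt2A, a metallothionein induced by glucocorticoids, fell on both of its probe sets, by 0.72 ± 0.104 and 0.59 ± 0.097, and Hsd11b1, which regenerates active glucocorticoid, fell by 0.58 ± 0.084 (0.0447). Fkbp5 was at -0.71 ± 0.147 (adjusted p = 0.0641), Nr3c1 at 0.40 ± 0.183 (0.26), Nr3c2, the mineralocorticoid receptor, at -0.45 ± 0.245 (0.332) and Bdnf at -0.32 ± 0.112 (0.177). On all 48 deposited arrays the count was 752.

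Several cell type lists moved in the same comparison. All 21 oligodendrocyte genes were higher (mean 0.39, adjusted p = 5.44e-11, 14 adjusted over the list alone) and 12 of 13 cortical layer neuron genes (mean 0.32, adjusted p = 6.13e-05, 8 higher and 1 lower adjusted over the list alone). Genes of astrocytes were lower, 14 of 15 (mean -0.21, adjusted p = 0.000153, 8 adjusted over the list alone). Genes of CA3 and CA2 pyramidal cells were lower too, 11 of 13 (mean -0.42, adjusted p = 0.0122, 4 adjusted over the list alone), as were those of ependymal cells, 9 of 10 (mean -0.32, adjusted p = 0.00629, 3 adjusted over the list alone), and of dentate granule cells, 8 of 10 (mean -0.40, adjusted p = 0.0393, 1 adjusted over the list alone). Oxidative phosphorylation genes were lower, 70 of 78 (mean -0.11, adjusted p = 6.08e-05), and so were glucocorticoid-responsive genes, 15 of 20 (mean -0.12, adjusted p = 0.0478, 3 adjusted over the list alone). Immediate early genes were higher, 18 of 27 (mean 0.23, adjusted p = 0.0393, 1 higher and 1 lower adjusted over the list alone). With an estimated correlation the adjusted p of the 12 lists that passed lay between 0.51 and 0.635. Immediate early genes were at 0.099 without NSt-Vin 3 (adjusted p = 0.222), 0.19 without St-Vin 1 (0.0526) and 0.17 without St-Vin 2 (0.105). Dentate granule cells were at -0.24, -0.31 and -0.29 without the same arrays (0.239, 0.0993 and 0.137). The glucocorticoid list missed without NSt-Vin 3, St-Vin 2 or St-Vin 3 (0.141, 0.097 and 0.0674). NSt-Vin was scanned on day 3 and St-Vin on day 4, no group has measured arrays on both days, and so stress and scan day cannot be told apart here. Leaving out NSt-Vin 1, 2 or 3 or St-Vin 2 left 0 probe sets, leaving out St-Vin 1 left 1, and leaving out St-Vin 3 gave 272.

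In motor cortex of the vinclozolin lineage, oxidative phosphorylation genes were lower with stress, 68 of 78 (mean -0.075, adjusted p = 2.74e-07, or 0.839 with an estimated correlation). Interneuron genes were lower too, 18 of 22 (mean -0.11, adjusted p = 1.26e-05, or 0.676 with an estimated correlation), with 2 members adjusted over the list alone. Leptomeningeal genes were higher, 14 of 16 (mean 0.20, adjusted p = 1.03e-05, or 0.839 with an estimated correlation), and immediate early genes lower, 22 of 27 (mean -0.076, adjusted p = 0.0143, or 0.839 with an estimated correlation). Only 1 NSt-Vin array shares scan day 2 with St-Vin, and scan day as a block amounts to leaving out the other one, NSt-Vin 1, with the spread taken from the other groups. The means then were -0.035 for oxidative phosphorylation (adjusted p = 0.0921), -0.073 for interneurons (0.0286), 0.22 for leptomeninges (0.00136) and -0.10 for immediate early genes (0.00712). The means rest on few arrays: without St-Vin 3 they were -0.036 (adjusted p = 0.0702), -0.057 (0.0663), -0.038 (0.79) and -0.035 (0.35) in that order. Immediate early genes also missed without NSt-Vin 3 (0.431) or St-Vin 1 (0.12). In the amygdala immediate early genes were lower too, 21 of 27 (mean -0.11, adjusted p = 0.000301, or 0.599 with an estimated correlation). Without NSt-Vin 2 the mean was -0.045 (adjusted p = 0.131), and 18 of 18 striatal genes were higher in the same comparison (mean 0.42, adjusted p = 0.00391, or 0.697 with an estimated correlation). In CA3, 30 of 34 glutamate genes (mean -0.12, adjusted p = 0.00722, or 0.863 with an estimated correlation, 4 adjusted over the list alone) were lower. So were 15 of 15 circadian clock genes (mean -0.14, adjusted p = 0.00722, or 0.565 with an estimated correlation). The glutamate mean was -0.068 without NSt-Vin 1 (adjusted p = 0.0351) and also without St-Vin 3 (0.0499), and the clock list missed without NSt-Vin 3 (0.068). Olfactory receptor genes, a class largely silent in brain, were higher there, 854 of 1098 (mean 0.065, adjusted p = 2.85e-21, or 0.357 with an estimated correlation). This list stood at 6.60 in CA3, below the array medians of 7.34 to 7.39. With the dim filter list calls in this CA3 comparison fell from 10 to 3. limma called 0 probe sets in these 3 areas, with 552 (amygdala), 856 (motor cortex) and 3836 (CA3) below an unadjusted p of 0.05.

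Averaged over lineage, 2 probe sets differed with stress in motor cortex (1 higher, 1 lower, 3865 below an unadjusted p of 0.05, 0 with the replicate block and 0 with scan day as a block). The named one, Mettl27, fell by 0.32 ± 0.039 (adjusted p = 0.0367). All 48 deposited arrays gave 560 there and 773 in CA1, where the 46 gave 0 (4624 below an unadjusted p of 0.05). In CA1 Prodh, the proline dehydrogenase (-0.46 ± 0.053), Mt2A (-0.54 ± 0.078) and E2f5 (-0.44) came nearest, at adjusted p = 0.0911. The glucocorticoid-responsive list was lower in CA1, 15 of 20 (mean -0.11, adjusted p = 0.00612, or 0.432 with an estimated correlation), with 6 members adjusted over the list alone. Astrocyte genes were lower there too, 14 of 15 (mean -0.16, adjusted p = 5.21e-05, or 0.432 with an estimated correlation), with 7. Markers of other tissue passed too: means of -0.32 for CA3 and CA2 cells (0.00717), -0.26 for ependyma (0.000754), -0.72 for choroid plexus (0.00125), 0.21 for oligodendrocytes (4.1e-07) and 0.22 for cortical layer neurons (0.000108). limma called 0 in the amygdala (1130 below an unadjusted p of 0.05), in CA3 (2887) and in the mean of areas (2260). The stress-axis list (means from -0.032 to 0.060, smallest adjusted p = 0.112) and the sex steroid list (means from -0.064 to 0.044, smallest adjusted p = 0.327) passed in no comparison of any area or of the mean of areas.

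In the mean of areas, immediate early genes were higher in the vinclozolin lineage both without stress, 20 of 27 (mean 0.079, adjusted p = 1.16e-05, or 0.344 with an estimated correlation), and with it, 21 of 27 (mean 0.090, adjusted p = 2.56e-06, or 0.22 with an estimated correlation). The former mean was 0.036 without the choroid-rich arrays (adjusted p = 0.0216), 0.046 without NSt-Vin 1 (0.000566) and 0.052 without NSt-Con 3 (0.000609). Npas4 was at 0.40 ± 0.073 in stressed rats (adjusted p = 0.892). Under stress all 13 genes of CA3 and CA2 pyramidal cells were lower in the vinclozolin lineage (mean -0.11, adjusted p = 4.2e-05, or 0.154 with an estimated correlation). With stress 14 of 15 clock genes were higher in the control lineage (mean 0.088, adjusted p = 2.17e-05, or 0.982 with an estimated correlation, and mean 0.049 with adjusted p = 0.0168 without the choroid-rich arrays). In the vinclozolin lineage 72 of 78 oxidative phosphorylation genes were lower with stress (mean -0.051, adjusted p = 0.00143) and 20 of 21 genes of endothelium and pericytes higher (mean 0.057, adjusted p = 3.94e-08), at 0.773 and 0.741 with an estimated correlation. Without NSt-Vin 1, which leaves 1 NSt-Vin pool, the oxidative phosphorylation mean was 0.015 (adjusted p = 0.169). limma called 0 probe sets in these 4 comparisons, with 852 and 1204 below an unadjusted p of 0.05 for lineage without and with stress, and 1834 and 1663 for stress in the control and the vinclozolin lineage.

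The stress difference varied between areas for 320 probe sets in the F test, 172 of them with 1 symbol (5361 below an unadjusted p of 0.05, and 1179 on all 48 deposited arrays). Igfbp6 led (adjusted p = 2.5e-05), at -0.61 in motor cortex, 0.32 in CA1, 0.11 in CA3 and -0.020 in the amygdala. Without the choroid-rich arrays 13 probe sets passed, and leaving out 1 pool gave 16 (without St-Vin 2) to 664 (without NSt-Con 1). In motor cortex, and for St-Vin in CA1, stress goes with a change of scan day, while the amygdala and CA3 were each scanned on 1 day, so these differences between areas may be those of scan day.

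The interaction asks whether the lineage difference changed with stress. Oligodendrocyte genes showed it in 3 areas. In CA1 their mean lineage difference turned from -0.18 without stress to 0.18 with it (change 0.37, higher in 21 of 21 genes, adjusted p = 1.02e-10), where a scan-day offset of St-Vin would appear in full as interaction. In motor cortex it went from -0.020 to 0.14 (change 0.16, higher in 19 of 21, adjusted p = 0.00549), but the change was 0.023 without St-Vin 1 (0.633) and 0.11 without NSt-Con 1 (0.12). In the amygdala it turned from 0.047 to -0.11 (change -0.16, lower in 19 of 21, adjusted p = 2.03e-08). The adjusted p was 0.721, 0.968 and 0.848 with an estimated correlation. In CA3 the glutamate genes turned from 0.072 to -0.063, lower in 29 of 34 (change -0.13, adjusted p = 0.0019, or 0.747 with an estimated correlation). The clock genes turned from 0.053 to -0.077, lower in 15 of 15 (change -0.13, adjusted p = 0.0268, or 0.747 with an estimated correlation). Without NSt-Con 3 neither passed (adjusted p = 0.123 and 0.113), nor did the clock genes without NSt-Vin 3, St-Con 3, St-Vin 2 or St-Vin 3. limma called 0 probe sets for the interaction in each area and in the mean of areas, with 331 (amygdala), 1534 (motor cortex), 1124 (CA1), 1805 (CA3) and 1249 (mean) below an unadjusted p of 0.05. The nearest were Or6c219 in motor cortex (-0.89 ± 0.130, adjusted p = 0.49), Sh3bp4 in CA1 (0.73 ± 0.099, adjusted p = 0.509) and Epha5 in CA3 (-0.40 ± 0.072, adjusted p = 0.752). With the replicate block CA1 gave 135 probe sets, 62 higher and 73 lower, with Sh3bp4 at 0.76 (adjusted p = 0.0197), again on 2 stressed pairs and with the same scan-day limit. Across all probe sets, which are not independent replicates, the lineage differences without and with stress correlated at r = 0.224 (rho = 0.191) in the amygdala, -0.0248 (0.00119) in motor cortex, -0.0206 (-0.021) in CA1, -0.0686 (-0.15) in CA3 and -0.0976 (-0.11) in the mean of areas.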

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

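Chosen only after the results were seen were the tests of explanations in the next 3 paragraphs and the splits of motor cortex, CA1 and the mean of areas, while the splits of the amygdala and CA3 and the interaction tests of the lists were planned.

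The immediate early genes were higher in the vinclozolin lineage in 6 of 6 dyad groups, by 0.0923 over the areas. Of the 32 ways of swapping the lineage labels within dyad groups, 1 gave a mean as large, the real one (highest other 0.0698), which restates that all 6 differences are positive, with an exact share of 0.03125. Only the real labels, 1 of 32, gave any of the fixed lists so large a mean over its standard error (11, highest other 5.98), which argues against the choice of the strongest list as the cause. In the amygdala and CA3, each scanned on 1 day, the mean was 0.0565 ± 0.0236 (SE, n = 6, exact two-sided p = 0.0938, 5 of 6 dyad groups higher). Scan day as the whole cause is thus not excluded. A change within cells and a change in the cell makeup of the punches cannot be told apart: regression of 22 pairs on 5 cell type lists, which do not cover every type, left 0.0762 ± 0.0204 (jackknife SE) of 0.0931, so a lasting effect of lineage on neuronal activity may be the cause only as an untested hypothesis (adjusted p = 0.101 with an estimated correlation).

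The stress difference of the control lineage in motor cortex (174 probe sets) goes with a change of scan day, from day 1 in NSt-Con to day 2 in St-Con. Whether choroid plexus tissue in NSt-Con 1 is the cause cannot be told. The probe sets were called with that array, and their mean change was 0.418 without it and 0.414 with it. Scan day and stress cannot be told apart with these arrays: the NSt-Vin array of day 2 scored -0.045 relative to that of day 1 on a scale where a full day effect would give 1, but they are single arrays. With scan day as a block the mean change was 0.426 ± 0.209, against 0.414 ± 0.143 without (SD over probe sets), and all 174 calls ended because the median SE rose from 0.0633 to 0.129, with 131 still below an unadjusted p of 0.05. An effect of stress thus may remain beside one of scan day, untested.

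The stress difference of the vinclozolin lineage in CA1 (138 probe sets) went with lower markers of CA3 and CA2 cells, dentate granule cells and ependyma, which neighbour CA1. The CA1 pyramidal list stood at 8.95, 9.014 and 8.374 in NSt-Vin 1 to 3 and at 9.185, 9.325 and 8.842 in St-Vin 1 to 3. Less CA3-side tissue in the St-Vin punches stays open. The stress difference of the called genes, which are not independent, correlated with CA3 minus CA1 levels at r = -0.136 (rho = -0.147). Leaving out 1 array gave -0.197 to -0.00486. This cannot decide it, as the CA1 pyramidal list was higher in CA3 (9.276) than in CA1 (8.863). Scan day cannot be told apart from stress, since 0 groups have measured arrays on both day 3 and day 4. Stress itself stays an untested explanation, and 4 of the 6 arrays, NSt-Vin 1, 2 and 3 and St-Vin 2, each left 0 probe sets when left out.

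Comparisons of 3 arrays with 3 allow 10 splits of the samples, too few for a share under 0.05. The real split gave 174 probe sets for stress in control-lineage motor cortex and 138 for stress in vinclozolin-lineage CA1, with 1 of 10 splits as large and a highest other of 0 in both. The real count and the highest other were 0, with 10 of 10 splits as large, for both lineage and both stress differences in the amygdala and in CA3, for lineage in stressed motor cortex and for lineage in non-stressed CA1.

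For the averages and the interaction 100 splits were drawn, and chance cannot be excluded for any of these counts. For the stress average of motor cortex 5 of 100 splits were as large as the real count of 2 (highest other 69). The real count was 0 elsewhere, so 100 of 100 were as large. The highest other for the interaction was 1 in the amygdala, 386 in motor cortex, 475 in CA1, 477 in CA3 and 967 in the mean of areas. For the lineage average it was 712, 78, 539, 477 and 2225 in the same order, and for the stress average 2466 in the amygdala, 196 in CA1, 334 in CA3 and 758 in the mean. Splits that call so many point to a structure of the samples other than lineage and stress. The amygdala split with 2466 parts dyad groups 1, 4 and 5 from 2, 3 and 6, as the striatal list does. For lineage and interaction, splits that part as many dyad pairs as the real one (4 of the 10, and 11 to 18 of the 100) had a highest other of 0, except 1 for the interaction in motor cortex.

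The remaining values come from the list test of the interaction: the lineage difference (vinclozolin minus control) changed between non-stressed and stressed rats by the mean log2 given, at the preset correlation of 0.01. With an estimated correlation none passed, at adjusted p = 0.848 in the amygdala, 0.968 in motor cortex, 0.721 in CA1, 0.747 in CA3 and 0.71 in the mean of areas, except 0.977 for oxidative phosphorylation in motor cortex and, in CA3, 0.691 for olfactory receptors and leptomeninges and 0.81 for choroid plexus and striatal genes. Only oligodendrocytes in the amygdala and CA1, olfactory receptors and leptomeninges in CA3, and endothelium in the mean of areas passed without each array in turn and without the choroid-rich arrays.

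In the amygdala the changes were -0.050 for immediate early genes, 0.35 for blood cells and -0.10 for neurons of the central amygdala and bed nucleus (adjusted p = 0.0396 each). Oligodendrocytes were at -0.16 (2.03e-08) and choroid plexus at 0.20 (0.0214), or -0.084 without the choroid-rich array (0.596). In motor cortex they were -0.089 for GABA genes (0.0279), -0.10 for clock genes (0.0412, or 0.0824 with the replicate block) and -0.047 for ribosomal proteins (0.0412, or 0.386 with the replicate block). Oxidative phosphorylation was at -0.060 and oligodendrocytes at 0.16 (both 0.00549), and choroid plexus at 0.97 (3.29e-05). Without NSt-Con 1, the choroid-rich array, choroid plexus was at 0.30 (0.0909).

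In CA1, where St-Vin has its own scan day, oligodendrocyte genes changed by 0.37 (1.02e-10), choroid plexus by 0.87 (2.5e-05), leptomeninges by 0.28 (0.000618) and cortical layer neurons by 0.20 (0.0138). Without the choroid-rich arrays choroid plexus turned to -0.36 (0.0201) and leptomeninges to -0.027 (0.924). In CA3 glutamate genes were at -0.13 (0.0019), cholesterol synthesis at -0.13 (0.00981) and clock genes at -0.13 (0.0268). Olfactory receptors were at 0.055 (6.44e-13), endothelium and pericytes at 0.058 (0.00658), choroid plexus at 0.47 (0.00146, or -0.38 with 0.99 without NSt-Con 3) and leptomeninges at 0.28 (1.16e-05). Striatal neurons were at 0.25 (0.0124, or -0.030 with 0.874 without NSt-Con 2) and thalamic and habenular neurons at 0.11 (0.0243).

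In the mean of areas GABA genes changed by -0.10 and glutamate genes by -0.060 (both 0.0179). Clock genes were at -0.085 (0.0285, or 0.153 with the replicate block), MHC and interferon genes at 0.021 (0.0326, or 0.0913 with the block) and astrocytes at -0.075 (0.0109, or 0.255 with the block). Olfactory receptors were at 0.035 (4.96e-10), oligodendrocytes at 0.073 (0.00578) and endothelium and pericytes at 0.074 (8.25e-06). Choroid plexus was at 0.57 (2.75e-08), blood cells at 0.14 (0.0313) and leptomeninges at 0.15 (0.000115). Without the choroid-rich arrays these were -0.13 (0.755), 0.091 (0.0978) and 0.031 (0.136). Neurons moved by -0.22 for the striatum (0.00148), -0.11 for CA3 and CA2 (0.0171), 0.069 for thalamus and habenula (0.0326) and 0.071 for cortical layers (0.0424). The striatal change turned to 0.038 with all 48 arrays (0.588) and 0.093 with area-centred pools (0.231). Between areas the F test of limma called 0 probe sets for lineage (1316 below an unadjusted p of 0.05) and 320 for stress (5361).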

How the results depend on the processing

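Chosen only after the data were seen were counting identical probe sets once, leaving out the choroid-rich arrays, keeping all 48 deposited arrays, the replicate block with an estimated correlation, and area-centred pools. The numbers of genes past the threshold rest on few arrays and moved most, while directions mostly held: of 419 results that are not counts, 43 turned in direction when 1 array was left out and 40 in another setting. Named genes kept direction and side of the threshold in 151 of 151 cases with identical probe sets counted once, in 149 with trend and robust settings, where 2 more passed, and in 137 after quantile normalization, where 13 no longer passed. The dim filter left 102 as they were and took 15 below the threshold. Of 270 list shifts that passed, 224 also passed with the dim filter, 249 with the replicate block and 166 without the choroid-rich arrays. The direction of a list is that of its test against all other genes, so a mean can keep its sign where the test turns. The replicate block changed 86 list calls (21 lost, 65 gained) and the counts given for it below, took 8 named genes below the threshold and 6 above it, and changed no other call. Scan day as a block was not run in CA1, where no group has measured arrays on both days, nor in the amygdala and CA3, each scanned on 1 day. Dim probe sets limit the single genes: with the dim filter the counts in motor cortex and CA1 fell to 50 and 16. Values in brackets after a count are those of the report. The cause of a change was not tested unless the setting itself leaves out arrays or probe sets.

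With 1 fit of all areas, the counts were 2 (0) for lineage without stress in motor cortex, 591 (174) for stress in Con in motor cortex, 3 (0) for the lineage average in motor cortex, 179 (2) for the stress average in motor cortex and 1598 (138) for stress in Vin in CA1. Further counts were 1115 (0) for the stress average in CA1.

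On all 48 deposited arrays, the counts were 1 (0) for lineage without stress in motor cortex, 1027 (174) for stress in Con in motor cortex, 560 (2) for the stress average in motor cortex, 752 (138) for stress in Vin in CA1 and 773 (0) for the stress average in CA1. Further counts were 12 (0) for stress in Vin in the mean of areas, 1 (0) for the stress average in the mean of areas, 1 (0) for the F test of lineage by area and 1179 (320) for the F test of stress by area. In that setting Fkbp5 was at 0.0083 for the lineage average of the mean of areas and the lineage differences of the mean of areas correlated at -0.00934. The list means that turned in direction were for the interaction in the mean of areas striatal neurons 0.038.

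With the filter on dim probe sets, the counts were 50 (174) for stress in Con in motor cortex, 0 (2) for the stress average in motor cortex, 16 (138) for stress in Vin in CA1 and 211 (320) for the F test of stress by area.

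With trend and robust settings, the counts were 385 (174) for stress in Con in motor cortex and 53 (2) for the stress average in motor cortex.

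After quantile normalization, the counts were 390 (174) for stress in Con in motor cortex, 1 (2) for the stress average in motor cortex, 44 (138) for stress in Vin in CA1 and 516 (320) for the F test of stress by area. In that setting Fkbp5 was at 0.0027 for the stress average of the mean of areas.

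With scan day as a block, the counts were 0 (174) for stress in Con in motor cortex and 0 (2) for the stress average in motor cortex. The list means that turned in direction were for stress in Vin in motor cortex cholesterol biosynthesis 0.0087 and olfactory receptors -0.027, for the stress average in motor cortex oxidative phosphorylation 0.016 and endothelial cells -0.044.

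Without the choroid-rich arrays, the counts were 19 (174) for stress in Con in motor cortex, 1 (2) for the stress average in motor cortex, 305 (138) for stress in Vin in CA1, 1 (0) for lineage without stress in CA3 and 1 (0) for the lineage average in CA3. Further counts were 13 (320) for the F test of stress by area. In that setting Fkbp5 was at 0.018 for the stress average of the mean of areas. The list means that turned in direction were for lineage with stress in the amygdala choroid plexus -0.083 and striatal neurons 0.33, for stress in Vin in the amygdala choroid plexus -0.13, for the interaction in the amygdala choroid plexus -0.084. Others were for the stress average in the amygdala choroid plexus -0.089, for the lineage average in motor cortex choroid plexus 0.10, for lineage without stress in CA1 circadian clock -0.028, olfactory receptors 0.041, endothelial cells 0.018, choroid plexus 0.24 and leptomeninges 0.072. Others were for stress in Con in CA1 immediate early genes -0.080, MHC and interferon response -0.011, olfactory receptors 0.036, endothelial cells -0.013, choroid plexus 0.069, ependymal cells -0.026, leptomeninges 0.029 and cortical layer neurons -0.036, for the interaction in CA1 choroid plexus -0.36, for the lineage average in CA1 olfactory receptors 0.014 and choroid plexus 0.064. Others were for the stress average in CA1 choroid plexus -0.11, for lineage without stress in CA3 choroid plexus 0.20, for stress in Con in CA3 choroid plexus 0.20. Others were for the interaction in CA3 choroid plexus -0.38, for the lineage average in CA3 choroid plexus 0.0066, for lineage without stress in the mean of areas choroid plexus 0.088 and leptomeninges 0.029. Others were for the interaction in the mean of areas choroid plexus -0.13, for the lineage average in the mean of areas choroid plexus 0.025 and striatal neurons 0.020.

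With the replicate block, the counts were 0 (2) for the stress average in motor cortex, 347 (0) for lineage with stress in CA1, 135 (0) for the interaction in CA1 and 112 (0) for the lineage average in CA1. The list means that turned in direction were for the lineage average in the mean of areas striatal neurons 0.022.

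With area-centred pools, the counts were 1 (0) for the stress average in the mean of areas. In that setting Fkbp5 was at 0.019 for the lineage average of the mean of areas. The list means that turned in direction were for lineage with stress in the mean of areas striatal neurons 0.015, for the interaction in the mean of areas striatal neurons 0.093.

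Within scan day 2, the list means that turned in direction were for stress in Vin in motor cortex cholesterol biosynthesis 0.0087 and olfactory receptors -0.027.

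With the replicate block and an estimated correlation, 0 list shifts passed (270). The list means that turned in direction were for the lineage average in the mean of areas striatal neurons 0.022.

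With an estimated correlation, 0 list shifts passed (270).

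Leaving out 1 array at a time moved counts. Stress in Con in motor cortex had 0 (without NSt-Con 3) to 19 (without NSt-Con 1). The lineage average in motor cortex had 0 (without NSt-Con 1) to 1 (without St-Vin 1). The stress average in motor cortex had 0 (without NSt-Con 3) to 9 (without St-Vin 1). Stress in Vin in CA1 had 0 (without NSt-Vin 1) to 272 (without St-Vin 3). The stress average in CA1 had 0 (without NSt-Con 2) to 6 (without St-Vin 3). Lineage without stress in CA3 had 0 (without NSt-Con 1) to 1 (without NSt-Con 2). Stress in Con in CA3 had 0 (without NSt-Con 1) to 1 (without NSt-Con 2). The interaction in CA3 had 0 (without NSt-Con 1) to 1 (without NSt-Con 2). The lineage average in CA3 had 0 (without NSt-Con 1) to 1 (without NSt-Con 3). Stress in Vin in the mean of areas had 0 (without NSt-Vin 1) to 2 (without NSt-Vin 3). The F test of lineage by area had 0 (without NSt-Con 1) to 1 (without St-Vin 1). The F test of stress by area had 16 (without St-Vin 2) to 664 (without NSt-Con 1). Correlations of the lineage differences without and with stress ran in the amygdala from 0.0109 (without NSt-Con 1) to 0.279 (without NSt-Con 3), in motor cortex from -0.108 (without St-Vin 2) to 0.0756 (without St-Vin 3), in CA1 from -0.188 (without NSt-Con 3) to 0.124 (without NSt-Vin 3), in CA3 from -0.183 (without St-Vin 2) to 0.114 (without St-Vin 3) and in the mean of areas from -0.223 (without St-Vin 2) to 0.056 (without St-Vin 3).

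In the mean of areas, control genes whose sign turned ran as follows. Nr3c1 ran from -0.0063 (without NSt-Vin 1) to 0.070 (without NSt-Vin 3) for the lineage average. Crh ran from -0.024 (without NSt-Vin 1) to 0.035 (without NSt-Vin 3) for the lineage average. Dnmt1 ran from -0.0017 (without NSt-Vin 1) to 0.082 (without NSt-Vin 3) for the lineage average. Esr1 ran from -0.031 (without NSt-Vin 1) to 0.0050 (without NSt-Vin 3) for the stress average. Nr3c1 ran from -0.0050 (without NSt-Vin 3) to 0.071 (without NSt-Vin 1) for the stress average. Crh ran from -0.0060 (without NSt-Vin 3) to 0.053 (without NSt-Vin 1) for the stress average. Fkbp5 ran from -0.062 (without St-Con 1) to 0.024 (without St-Con 2) for the stress average. Dnmt3a ran from -0.024 (without St-Con 2) to 0.0033 (without St-Con 1) for the stress average. Dnmt1 ran from -0.00042 (without NSt-Vin 3) to 0.083 (without NSt-Vin 1) for the stress average.

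List means whose direction turned were these. Olfactory receptors ran from -0.0031 (without St-Con 2) to 0.071 (without St-Con 3) for lineage with stress in the amygdala and -0.0018 (without NSt-Vin 1) to 0.051 (without NSt-Vin 3) for stress in Vin in the amygdala. Olfactory receptors ran from 0.0041 (without St-Con 2) to 0.041 (without St-Con 3) for the lineage average in the amygdala and -0.027 (without NSt-Vin 1) to 0.045 (without NSt-Vin 3) for stress in Vin in motor cortex. Olfactory receptors ran from -0.072 (without NSt-Con 1) to -0.0065 (without NSt-Con 3) for stress in Con in CA1 and -0.041 (without NSt-Vin 3) to 0.020 (without NSt-Vin 1) for lineage without stress in the mean of areas. Olfactory receptors ran from -0.014 (without NSt-Vin 1) to 0.046 (without NSt-Vin 3) for stress in Vin in the mean of areas and 0.0043 (without NSt-Vin 1) to 0.065 (without NSt-Vin 3) for the interaction in the mean of areas. Olfactory receptors ran from -0.017 (without NSt-Vin 1) to 0.014 (without NSt-Vin 3) for the stress average in the mean of areas. In the amygdala, choroid plexus was lowest without St-Vin 3 and highest without St-Vin 2. It ran from -0.083 to 0.35 for lineage with stress and -0.13 to 0.31 for stress in Vin. The interaction ran from -0.084 to 0.35 and the stress average from -0.089 to 0.13. Choroid plexus ran from -0.41 (without NSt-Con 2) to 0.10 (without NSt-Con 1) for the lineage average in motor cortex and -1.12 (without NSt-Con 1) to 0.20 (without NSt-Con 3) for lineage without stress in CA3. In CA3 choroid plexus ran between its values without NSt-Con 1 and without NSt-Con 3. These were -1.12 and 0.20 for stress in Con, 0.94 and -0.38 for the interaction, and -0.65 and 0.0066 for the lineage average. Striatal neurons ran from -0.87 (without St-Con 3) to 0.33 (without St-Vin 3) for lineage with stress in the amygdala and -0.37 (without NSt-Con 1) to 0.12 (without NSt-Con 2) for lineage without stress in CA3. MHC and interferon response ran from -0.0035 (without NSt-Vin 1) to 0.048 (without NSt-Vin 3) for stress in Vin in the amygdala and -0.051 (without NSt-Vin 3) to -0.00091 (without NSt-Vin 1) for lineage without stress in the mean of areas. MHC and interferon response ran from -0.0038 (without NSt-Vin 1) to 0.046 (without NSt-Vin 3) for the interaction in the mean of areas and -0.028 (without NSt-Vin 3) to -0.0028 (without NSt-Vin 1) for the lineage average in the mean of areas. Leptomeninges ran from -0.088 (without St-Vin 3) to 0.29 (without St-Vin 2) for lineage with stress in motor cortex and -0.038 (without St-Vin 3) to 0.34 (without St-Vin 2) for stress in Vin in motor cortex. Cholesterol biosynthesis ran from -0.15 (without NSt-Vin 3) to 0.012 (without St-Vin 3) for stress in Vin in motor cortex and -0.023 (without NSt-Vin 1) to 0.10 (without NSt-Vin 3) for lineage without stress in the mean of areas. Oligodendrocytes ran from -0.045 (without St-Vin 1) to 0.22 (without St-Vin 3) for stress in Vin in motor cortex and -0.0088 (without St-Vin 1) to 0.12 (without St-Vin 3) for the lineage average in motor cortex. Endothelial cells ran from -0.036 (without St-Vin 3) to 0.16 (without NSt-Vin 3) for stress in Vin in motor cortex. Oxidative phosphorylation ran from -0.12 (without NSt-Vin 3) to 0.015 (without NSt-Vin 1) for stress in Vin in the mean of areas and -0.051 (without NSt-Vin 1) to 0.014 (without NSt-Vin 3) for the lineage average in the mean of areas. Oxidative phosphorylation ran from -0.069 (without NSt-Vin 3) to -0.0037 (without NSt-Vin 1) for the stress average in the mean of areas.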

Other observations

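The list tests here were planned, and which of them are given was chosen after their values were seen. Averaged over lineage, heat shock and chaperone genes were lower after stress in CA1, 16 of 18 (mean -0.10, adjusted p = 0.0126, or 0.477 with an estimated correlation and 0.0577 without St-Con 1). They were lower in CA3 too, 16 of 18 (mean -0.067, adjusted p = 0.0386, or 0.867 with an estimated correlation), but without the choroid-rich array the CA3 mean was -0.038 (adjusted p = 0.364), and it also missed without NSt-Vin 3, St-Con 1, St-Con 2 or St-Vin 2 (0.118, 0.0583, 0.148 and 0.214). Clock genes went opposite ways in these areas. In CA1 13 of 15 were higher (mean 0.17, adjusted p = 0.00011, or 0.477 with an estimated correlation, and 0.094 with adjusted p = 0.0197 without the choroid-rich arrays). In CA3 15 of 15 were lower (mean -0.073, adjusted p = 0.0184, or 0.867 with an estimated correlation and 0.0879 with the dim filter), and they missed without NSt-Vin 3, St-Con 1 or St-Vin 2 (0.1, 0.0583 and 0.0826). The difference between the areas was not tested for lists, and these areas were scanned on different days.

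In the amygdala 23 of 28 genes of neurotrophic factors and plasticity were lower after stress (mean -0.066, adjusted p = 0.00351, or 0.597 with an estimated correlation), led by Syp, synaptophysin, at -0.25 ± 0.068. The striatal list was higher in the same arrays, 18 of 18 (mean 0.51, adjusted p = 7.77e-07, or 0.597 with an estimated correlation). Leaving out 1 array gave means from -0.080 to -0.053, with the adjusted p at most 0.0173. Microglia genes were higher there, 17 of 24 (mean 0.033, adjusted p = 0.00775, or 0.597 with an estimated correlation), but at 0.014 without St-Con 3 (adjusted p = 0.271), 0.021 without NSt-Vin 1 (0.163) and 0.022 without St-Vin 3 (0.106). In the mean of areas the olfactory receptor list moved by a mean of -0.0015 and a median of -0.0020, while its test against all other genes came out higher (adjusted p = 0.0134, or 0.91 with an estimated correlation), so the signs differ.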
